A study of Oryza sativa with 18 samples.

How the data were processed

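Total RNA of rice seedlings (Oryza sativa indica, cultivar IR64) was measured on 18 single-colour Agilent microarrays of 60-base probes, 1 array per biological replicate. Per the labels, seedlings grew normally in hydroponics for 5 days, were kept in solution with 0.798 mM CaCl2 (sufficient) or without CaCl2 (deficient) for 5 or 14 days, and some of the deficient seedlings then received 0.798 mM CaCl2 for 6 h (resupplied). Each of the 6 groups had 3 biological replicates, and 500 ng of RNA was labelled with Cy3. The samples were grouped by their titles. The treatment field of the sufficient day 14 samples describes deficiency with resupply, which conflicts with their title, source name and description.

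Each deposited array file holds the intensity of every spot as Agilent Feature Extraction 10.7.3.1 wrote it (protocol GE1_107_Sep09, scanner G2505C, array design 031380). Per the file headers, the processed intensity had local background subtraction switched off, and spatial and multiplicative detrending switched on. The value table deposited by the authors holds the same processed intensity without further scaling: 59803 probes matched, with a Pearson correlation across probes of at least 0.9998. No count or read depth exists for an array, so the number of arrays limits the precision.

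The processed signal of 61657 non-control spots was averaged by probe (59805 probes), taken to log2, and scaled by subtracting the 75th percentile of each array. A probe was tested when the Feature Extraction flag put it well above background on all 3 arrays of at least 1 group, which left 46649 probes of 32039 genes. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the plots. One linear model with 6 group means was fitted to the 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, 12 residual and 1.81 prior degrees of freedom), without a block. The p-values of each comparison were adjusted by the Benjamini-Hochberg method over the 46649 probes, and a probe was called at an adjusted p below 0.05. Each p-value of a probe or gene rests on the spread among 3 biological replicates per group. Standard errors (SE) of log2 fold changes come from the moderated spread of this model.

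The 9 comparisons were deficient against sufficient at each day, resupplied against deficient at each day, resupplied against sufficient at each day, the difference between days of the deficiency effect and of the resupply effect, and day 14 against day 5 in sufficient seedlings. A gene with several probes was represented by the tested probe with the highest mean signal. Genes are given by the identifiers and descriptions of the array annotation, with positions on build IRGSP5. None of the 4008 probes with a RefSeq accession matched the gene table at hand, so no symbols are given.

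Genes were named by a rule. In each of the first 4 comparisons, the 6 called genes with the largest positive and the 6 with the largest negative log2 fold change were taken among genes with an informative description whose 3 values in one group all lay beyond the 3 of the other, which chance gives for 10% of genes. The other 5 comparisons took 3 genes each way. From each fixed list with at least 3 called members came the 2 members with the largest change and the largest in the other direction. The measured circadian clock genes were added to all of these. Where one group lay below background on all 3 of its arrays, the fold is given as a bound, computed after raising each value of that group to the lowest signal that any probe well above background had on the same array. No bound was computed for differences between days.

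A set of 35 gene lists, chosen from the descriptions of the annotation, was tested with camera of limma against all other genes, with a preset correlation between genes of 0.01. With this preset the p-value of a list rests on the spread among genes, not on that among replicates. Lists with fewer than 5 measured genes were not tested, which left 32. The p-values were adjusted over the 128 tests of the first 4 comparisons, and over the tests of the other 5 comparisons as a second family. Camera with a correlation estimated from the residuals gave no list an adjusted p below 0.05 in any of the 9 comparisons. The fry test, whose p-value asks whether the genes of a list moved one way on balance without comparing them with other genes, was also run.

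The groups, comparisons, lists, naming rule and alternatives were chosen before the data were examined, apart from those named here. The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the value table of the authors, no filter, a filter on all 18 arrays, removal of spots marked as outliers, a replicate block, a slide block, a trended and robust prior, array weights, a fit of only the groups compared, an adjusted p below 0.01, a minimum change of 2-fold, and each array left out in turn. A block for scan batch was identical to the slide block and was not run apart. Leaving resupplied day 5 replicate 1 out of the filter, scaling and fit, alone or with another scaling, was added after its signal had been seen, as were the slide block and further scalings for the gene lists.

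The 18 arrays lay on 3 slides. Slide 1 held all sufficient and deficient day 5 arrays and resupplied day 5 replicates 1 and 2. Slide 2 held resupplied day 5 replicate 3, all sufficient day 14 arrays and deficient day 14 replicates 1 and 2. Slide 3 held deficient day 14 replicate 3 and all resupplied day 14 arrays. With slide as a block, each comparison within a day other than resupplied against sufficient at day 14 came only from arrays that shared a slide. For the resupplied group at day 5 these were replicates 1 and 2.

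The model was tested on simulated data with 67 probes changed by 2-fold, 67 by 4-fold and 66 by 16-fold among 46649. For the first 4 comparisons it recovered 44.8% to 55.2% of the 2-fold changes, 74.6% to 83.6% of the 4-fold changes and 93.9% to 97.0% of the 16-fold changes, with 0 called in the wrong direction. Far fewer probes were changed than the real comparisons called, and the simulated noise was alike on all arrays. These rates therefore do not measure how many real changes were found.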

Results

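Transcript levels were measured on 18 arrays of rice seedlings that were calcium-sufficient, calcium-deficient, or deficient and resupplied with calcium for 6 h, at day 5 and at day 14. Each of the 6 groups had 3 biological replicates. The stated aim was to find calcium-responsive genes of metabolism, signalling, transcription and transport. On the 15 arrays outside the resupplied day 5 group, 71.6% to 78.8% of 61657 spots lay well above background. Resupplied day 5 replicate 1 had 98.9%, a median signal of 728 against 214 to 311 on the other 17 arrays, and 1023 non-uniform spots against 4 to 59. It was kept, and values without it are given for some results. Across probes, which are not independent replicates, replicates of 5 groups correlated at r = 0.981 to 0.991 and those of resupplied day 5 at 0.923 to 0.979. The first 2 principal components held 41.4% and 25.2% of the variance.

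**Figure D1:**
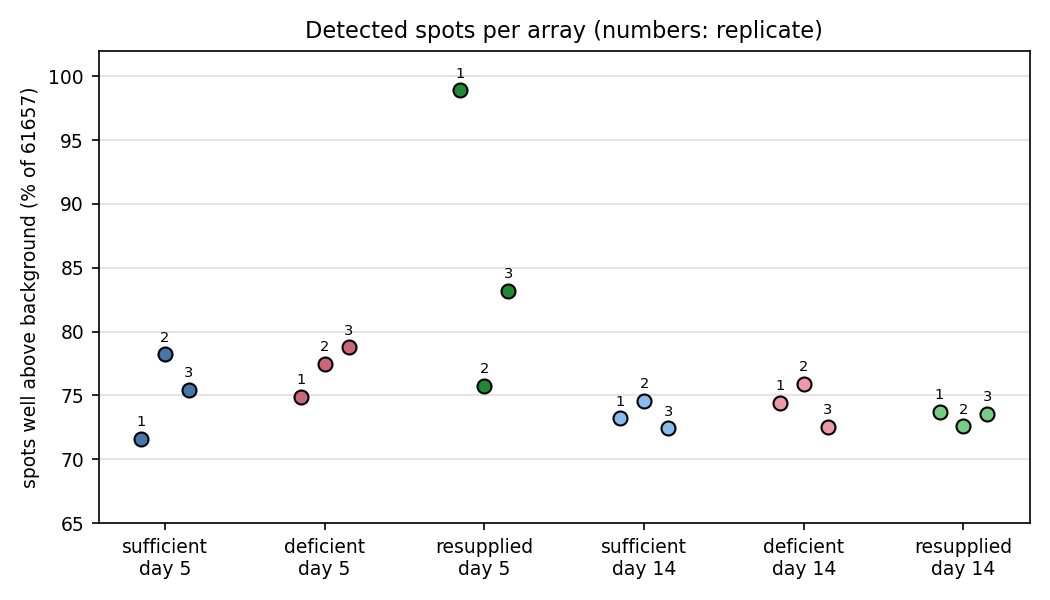
Percent of 61657 spots well above background on each of the 18 arrays, by group. Resupplied day 5 replicate 1 stands at 98.9%, and the 15 arrays of the other groups lie between 71.6% and 78.8%.

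**Figure D2:**
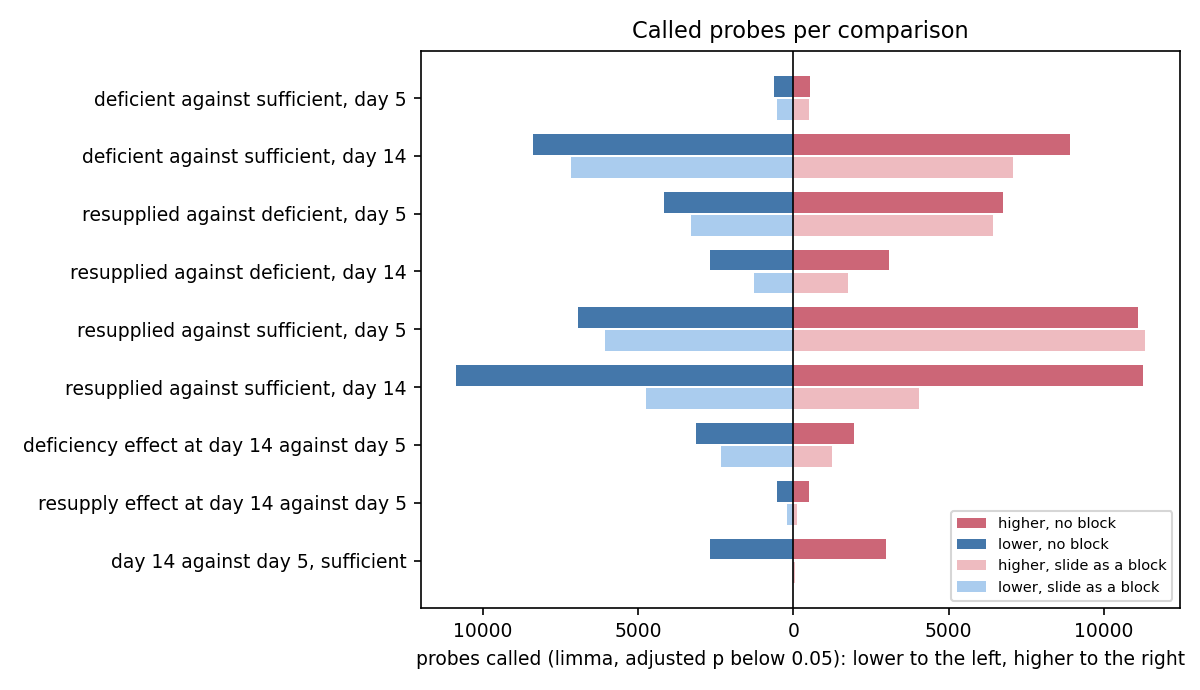
Number of probes called higher and lower (adjusted p below 0.05, limma) in each of the 9 comparisons, without a block and with slide as a block. Deficient against sufficient gave 1153 probes at day 5 and 17273 at day 14, and day 14 against day 5 in sufficient seedlings fell from 5656 to 80 with the block.

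The comparison of deficient with sufficient seedlings at day 5 asked which transcripts differed after 5 days without calcium. Os09g0483500, an EF-hand protein of the class that binds calcium ions, was 12.7-fold higher in deficient seedlings (log2 3.67 ± 0.70 SE, n = 3 per group here and throughout, adjusted p = 0.0171). Its probe lies on chromosome 9 from 19379042 to 19379101 and is named for the coding sequence and 3' untranslated region. Os11g0701400, a class III chitinase of the kind that acts on fungal walls, rose by log2 3.55 ± 0.72 (adjusted p = 0.0220), with the sufficient group above background on 1 of 3 arrays. Os05g0469600, similar to pyruvate decarboxylase of alcoholic fermentation, rose by log2 3.39 ± 0.66 (adjusted p = 0.0196), with the sufficient group above background on 2 of 3 arrays. Os06g0141600 (early nodulin 93 family) was at least 9.80-fold higher, Os07g0501100 (similar to chalcone synthase 2) at least 8.08-fold and Os02g0615300 (protein kinase) at least 4.78-fold, with adjusted p of 0.0149, 0.0389 and 0.00266. Os02g0764700, similar to ethylene-responsive transcription factor 4 (chromosome 2, 33060422 to 33060481), fell 17.3-fold (log2 -4.11 ± 0.52, adjusted p = 0.00216). Os06g0127100, dehydration-responsive element-binding protein 1C, changed by log2 -3.72 ± 0.65 (adjusted p = 0.0122). Os10g0418100, similar to plasma membrane calcium-transporting ATPase 8, a pump that moves calcium out of the cytosol, fell 8.07-fold (log2 -3.01 ± 0.44, adjusted p = 0.00517). A related pump, Os03g0203700, changed by log2 -1.15 ± 0.24 (adjusted p = 0.0256). Os08g0443800 (tetraspanin) and Os09g0535500 (similar to RING-H2 finger protein ATL1R) changed by log2 -3.88 ± 0.73 and -3.82 ± 0.58, and Os04g0554500 (similar to root protein RCc3) was at least 3.20-fold lower.

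At day 5, 343 of 32039 genes were called higher and 401 lower, and some genes of phenylpropanoid and jasmonate metabolism were among them. Of 59 lignin and phenylpropanoid enzymes 1 was higher and 2 lower (the same adjusted over the list alone), and of 42 jasmonate genes 1 and 3 (1 and 4), and neither list differed from other genes (adjusted p = 0.154 and 0.827, and 0.823 and 0.954 with an estimated correlation). Os04g0518400 (similar to phenylalanine ammonia-lyase) changed by log2 -1.76 ± 0.30, Os02g0697400 (similar to 4-coumarate-CoA ligase 1) by -1.51 ± 0.30, Os04g0447100 (similar to lipoxygenase) by -1.91 ± 0.33 and Os03g0180800 (Tify domain) by -2.28 ± 0.46, with adjusted p of 0.0108, 0.0202, 0.0114 and 0.0217. Os02g0527300, similar to heat shock transcription factor 31, fell 4.21-fold (log2 -2.07 ± 0.25, adjusted p = 0.00125). Among the auxin-responsive SAUR genes, Os08g0118500 was 6.43-fold higher (log2 2.69 ± 0.48, adjusted p = 0.0133) and Os10g0510500 was 2.74-fold lower (log2 -1.45 ± 0.15, adjusted p = 0.000599).

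Of 79 pathogenesis-related proteins and chitinases, 7 were higher, 0 lower and 72 not called at day 5 (14 higher and 3 lower adjusted over the list alone), and the list shifted upward with a median of log2 0.26 (adjusted p = 0.00244, and adjusted p = 0.643 with an estimated correlation). The other upward list was the cytosolic ribosomal proteins, with 0 of 146 called by limma (3 higher and 0 lower at an unadjusted p below 0.05), a median of 0.14 and adjusted p = 0.000294 (adjusted p = 0.906 with an estimated correlation). Of 28 calcium-dependent protein kinases, 0 were higher and 2 lower (0 and 3 adjusted over the list alone), with a median of -0.10 and adjusted p = 0.0146 (adjusted p = 0.643 with an estimated correlation). The photosystem and light-harvesting list shifted downward (median -0.14, adjusted p = 0.00244, and 0.734 with an estimated correlation) although 1 of its 63 members was called and that was higher. Of 7 root-expressed markers, 1 was lower (2 adjusted over the list alone), with a median of -0.79 and adjusted p = 0.00402 (adjusted p = 0.643 with an estimated correlation). Of 23 calcium pumps and cation/proton exchangers 3 were lower (1 higher and 3 lower adjusted over the list alone), and that list did not differ from other genes (adjusted p = 0.219). Under quantile normalization the kinases and the photosystem list lost their shifts (adjusted p of 0.0861 and 0.0926). The slide block left the 5 mean shifts at 0.46, 0.15, -0.27, -0.10 and -1.09, in the order given, with adjusted p of 0.00588, 0.000480, 0.0311, 0.00588 and 0.00129. These are means and the values above are medians, so their sizes cannot be compared.

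Across the array, 1153 of 46649 probes were called at day 5, 532 higher and 621 lower, and 594 of them changed at least 2-fold. A slide block gave 1027 calls (500 higher, 527 lower), and 30 of 32 named genes kept the call. The count fell to 176 and 298 without sufficient day 5 replicate 1 and 3, and to 332, 304 and 326 without deficient day 5 replicate 1, 2 and 3. It rose to 1951 without resupplied day 5 replicate 1, which is in neither group but widened the pooled spread. Of the named genes, 7 of 32 kept the call whichever array was left out, namely Os02g0615300, Os02g0764700, Os04g0554500, Os09g0535500, Os10g0418100, Os02g0527300 and Os10g0510500. Median scaling gave 173 higher and 382 lower (31.2% higher against 46.1%) and ended the call of Os03g0203700, and it gave 661 and 1405 without resupplied day 5 replicate 1. Normexp correction ended those of Os04g0554500, Os05g0469600, Os07g0501100 and Os11g0701400, quantile normalization those of Os03g0203700, Os07g0501100 and Os08g0118500, and the filter-free fit that of Os07g0501100.

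At day 14 the comparison of deficient with sufficient seedlings asked the same question after 14 days. Os05g0469600, similar to pyruvate decarboxylase (chromosome 5, 23158420 to 23158479), was 412-fold higher in deficient seedlings (log2 8.69 ± 0.66, adjusted p = 1.01e-06). Os08g0473900, similar to alpha amylase isozyme 3D, which releases sugar from starch, was 285-fold higher (log2 8.15 ± 1.09, adjusted p = 6.49e-05). Os11g0701400, the class III chitinase (chromosome 11, 30936590 to 30936649), was 268-fold higher (log2 8.07 ± 0.72, adjusted p = 2.59e-06). The EF-hand gene Os09g0483500 rose by log2 8.26 ± 0.70 (adjusted p = 1.79e-06, sufficient above background on 2 of 3 arrays) and Os01g0729600 (pyridoxal phosphate-dependent transferase) by 8.29 ± 0.77 (1 of 3 arrays). Os01g0342900, similar to an AMP-binding protein, was at least 104-fold higher (adjusted p = 7.87e-06). Os03g0843800 (methyl chloride transferase) fell 257-fold (log2 -8.00 ± 1.16, adjusted p = 0.000125), and Os11g0641800 (cupredoxin domain) was at least 104-fold lower. Os02g0240300 (similar to a class III peroxidase), Os02g0308400 (FAS1 domain), Os02g0194700 (similar to lipoxygenase) and Os04g0354600 (similar to acyl CoA reductase) changed by log2 -9.08 ± 0.85, -8.69 ± 0.99, -7.90 ± 1.17 and -7.88 ± 0.82, with the deficient group above background on 2, 1, 1 and 1 of 3 arrays.

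Genes of calcium transport and sensing moved both ways at day 14, when 5754 of all 32039 genes were called higher and 5377 lower. The vacuolar exchanger Os01g0557500 (cation/proton exchanger 1a; chromosome 1, 22702295 to 22702354) fell 4.38-fold (log2 -2.13 ± 0.24, adjusted p = 1.85e-05) and the pump Os04g0605500 fell 3.00-fold (log2 -1.58 ± 0.18, adjusted p = 2.21e-05). The plasma membrane pump Os03g0616400 rose by log2 0.47 ± 0.14 (adjusted p = 0.0153), a call that normexp and median scaling ended. Of the 23 pumps and exchangers 3 were higher and 5 lower (the same adjusted over the list alone). Os11g0141400 (calmodulin-like CaML3) changed by -0.82 ± 0.16 (adjusted p = 0.000925), and of 8 calmodulins 1 was higher and 2 lower. Os04g0560600 (similar to calcium-dependent protein kinase 3) changed by -1.65 ± 0.23 (adjusted p = 0.000104), and of 28 such kinases 4 were higher and 4 lower. Os02g0201700 (CBL-interacting protein kinase 14) fell 5.36-fold (log2 -2.42 ± 0.28, adjusted p = 1.93e-05), and of 18 CBL sensors and CIPK kinases 4 were higher and 5 lower. Of 20 calcium-permeable channels 2 were higher and 6 lower, with Os09g0431200 (glutamate receptor-like) at 1.55 ± 0.24 and Os07g0103100 (glutamate receptor 3.4-like) at -1.39 ± 0.13. Of 19 annexins and C2 proteins 4 were higher and 4 lower (5 and 4 adjusted over the list alone; the other 4 lists kept their counts). Annexin Os05g0382900 changed by -1.19 ± 0.17 and Os02g0753800 by 1.12 ± 0.22.

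Transporters of other ions and cell wall genes changed at day 14 as well. Os06g0701700, similar to cation transporter HKT1 (chromosome 6, 30415994 to 30416051), fell 25.9-fold (log2 -4.69 ± 0.39, adjusted p = 1.50e-06). Os03g0307200, nicotianamine synthase 2, which makes a metal chelator (chromosome 3, 10975664 to 10975723), was 47.4-fold higher (log2 5.57 ± 0.96, adjusted p = 0.000483), and ferric reductase-like Os04g0444800 was 6.79-fold lower (log2 -2.76 ± 0.20, adjusted p = 7.67e-07). The aquaporin Os09g0541000 (chromosome 9, 22195336 to 22195395) fell 11.4-fold (log2 -3.51 ± 0.60, adjusted p = 0.000426), and the nitrate transporter Os10g0554200 changed by -2.69 ± 0.32. Counts higher and lower, with those adjusted over the list alone in parentheses, were 4 and 11 of 34 potassium and sodium transport genes (4 and 12), 0 and 1 of 4 magnesium transporters (1 and 2), 4 and 1 of 12 iron uptake genes (4 and 1), 6 and 6 of 42 nitrate, ammonium, phosphate and sulfate transporters (5 and 6) and 1 and 5 of 7 aquaporins (1 and 5). For the wall they were 8 and 18 of 56 pectin genes (8 and 19), 6 and 9 of 51 expansins and xyloglucan endotransglucosylases (4 and 9), 2 and 7 of 13 cellulose synthases (3 and 7) and 12 and 12 of 59 lignin and phenylpropanoid enzymes (13 and 12). Os02g0537000, a pectinesterase inhibitor, fell 108-fold (log2 -6.75 ± 0.67, adjusted p = 6.46e-06), and Os01g0283700, similar to cinnamoyl-CoA reductase, was at least 11.1-fold lower.

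Defence genes rose more often than they fell at day 14. The chitinase D55710 was 250-fold higher (log2 7.96 ± 0.65, adjusted p = 1.41e-06), and of 79 pathogenesis-related proteins and chitinases 33 were higher and 8 lower (34 and 9 adjusted over the list alone), with a median of 0.45 (adjusted p = 0.00244, and adjusted p = 0.643 with an estimated correlation). Of 12 diterpenoid phytoalexin enzymes, which make antifungal compounds in rice, 10 were higher and 0 lower (10 and 1 adjusted over the list alone), with a median of 2.17 (adjusted p = 0.000597, and adjusted p = 0.643 with an estimated correlation). Among them Os12g0491800 (similar to ent-kaurene synthase 1A) was 16.5-fold higher (log2 4.05 ± 1.06, adjusted p = 0.00837). The allene oxide synthase Os02g0218800 of jasmonate synthesis was 9.58-fold higher (log2 3.26 ± 0.31, adjusted p = 4.88e-06). Higher and lower counts (adjusted over the list alone in parentheses) were 15 and 6 of 42 jasmonate genes (15 and 7), 4 and 1 of 10 ethylene synthesis genes (4 and 1), 9 and 12 of 53 auxin-responsive genes (9 and 12), 0 and 0 of 3 cytokinin response regulators (0 and 0, and 0 and 0 at an unadjusted p below 0.05), 25 and 17 of 110 class III peroxidases (25 and 17) and 13 and 11 of 52 glutathione S-transferases (13 and 11). They were 22 and 9 of 80 WRKY (22 and 9), 14 and 7 of 47 NAC (15 and 8) and 6 and 6 of 28 AP2/ERF and DREB transcription factors (7 and 6), 40 and 25 of 130 heat shock genes (42 and 26), 2 and 2 of 25 late embryogenesis proteins (1 and 2), and 8 and 5 of 16 senescence and sugar starvation genes (9 and 5). Os02g0770500 (WRKY 32-like) changed by 3.35 ± 0.66, Os05g0563000 (NAM domain) by -3.05 ± 0.28, Os09g0522000 (DREB 1B) by -3.39 ± 0.66 and Os03g0161900 (heat stress factor A-2-like) by -4.05 ± 0.40.

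Most photosystem genes were lower in deficient seedlings at day 14. Of 63 photosystem and light-harvesting genes 5 were higher and 45 lower (6 and 47 adjusted over the list alone), with a median of -1.14 (adjusted p = 1.12e-13, and adjusted p = 0.417 with an estimated correlation). Os12g0291200, similar to the Rubisco small chain (chromosome 12, 11275302 to 11275361), fell 8.49-fold (log2 -3.09 ± 0.46, adjusted p = 0.000162), and Os01g0869800, photosystem II subunit PsbS (chromosome 1, 39429191 to 39429250), fell 6.19-fold (log2 -2.63 ± 0.29, adjusted p = 1.42e-05). Of 37 core histones 1 was higher and 15 lower (1 and 16 adjusted over the list alone), with a median of -0.42 (adjusted p = 0.00342, and adjusted p = 0.741 with an estimated correlation). Histone H2A gene Os03g0279200 changed by -0.96 ± 0.16 (adjusted p = 0.000330). Of 146 cytosolic ribosomal proteins 33 were higher and 1 lower (12 and 1 adjusted over the list alone), with a median of 0.27 (adjusted p = 2.02e-05, and adjusted p = 0.866 with an estimated correlation). Cyclins and mitotic kinesins had 3 higher and 2 lower of 30 (2 and 2 adjusted over the list alone), and root-expressed markers 1 higher, a DNA repair helicase, and 3 lower of 7 (1 and 4). Of 4 clock genes 1 was higher and 1 lower (the same adjusted over the list alone). LHY-like Os04g0583900 changed by 1.94 ± 0.42 (adjusted p = 0.00259) and EARLY FLOWERING 4-like Os11g0621500 by -0.64 ± 0.17 (adjusted p = 0.00946), a call that median scaling ended. For the 27 other tested lists camera found no difference from other genes, with adjusted p of 0.0673 to 0.958 (0.643 to 0.986 with an estimated correlation). The fry test, which does not compare a list with other genes, called 7 of them: potassium and sodium transport, aquaporins, cellulose synthases and root-expressed markers downward, and NAC factors, heat shock genes and senescence genes upward. Median and mean differed in sign for the pumps and exchangers (0.07 and -0.24), the expansins (0.03 and -0.15) and ethylene synthesis (-0.12 and 0.27). The test pointed downward for lignin enzymes (0.02 and 0.01) and upward for the AP2/ERF and DREB factors (-0.02 and -0.15). With slide as a block the mean shifts of the chitinase, diterpenoid, photosystem, histone and ribosomal lists were 0.98, 1.99, -0.99, -0.45 and 0.18, with adjusted p of 0.00726, 0.000556, 4.15e-14, 0.00129 and 0.00726. The shifts given above for these lists are medians, so sizes with and without the block cannot be compared.

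In all, 17273 probes were called at day 14, 8894 higher and 8379 lower, and 7579 of them changed at least 2-fold. Under the slide block 14215 were called (7072 higher, 7143 lower), and 83 of 90 named genes kept the call. Of the genes given here, Os03g0616400 lost it when single arrays were left out. The difference between days was tested directly and is given among the comparisons of days.

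**Figure D3:**
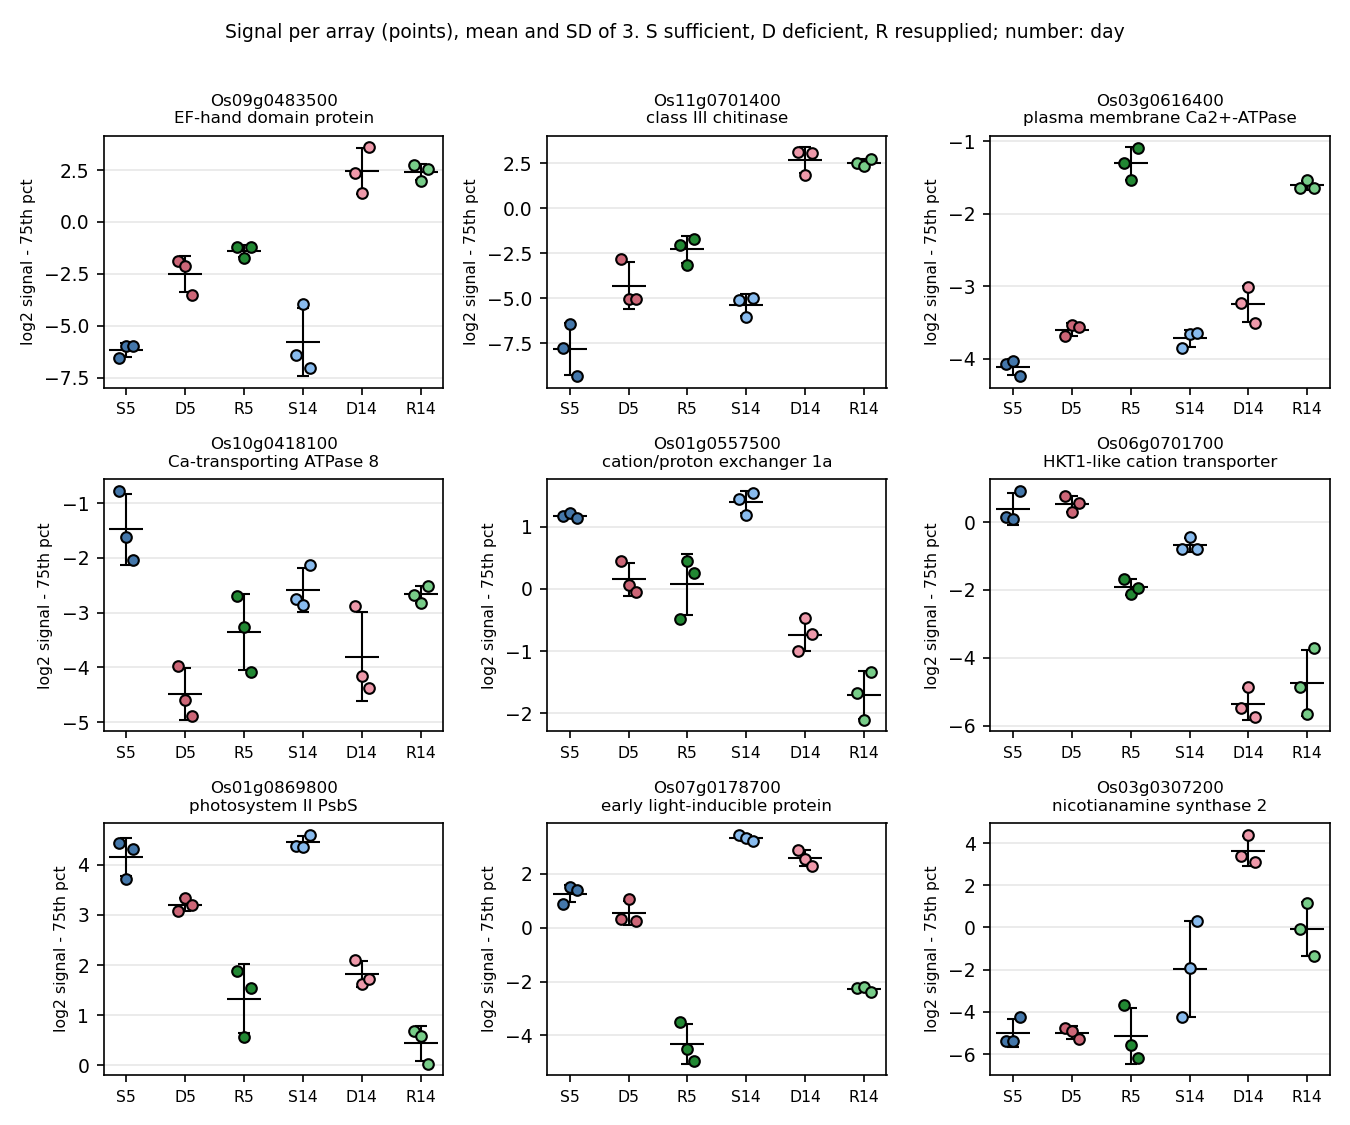
Scaled log2 signal of 9 named genes on each array (points), with the mean and SD of 3 replicates, in the 6 groups. Os09g0483500 lies higher in deficient than in sufficient seedlings at both days (log2 3.67 and 8.26), and Os03g0616400 rises on resupply at both days (log2 2.29 and 1.64).

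The comparison of resupplied with deficient seedlings at day 5 asked which transcripts moved within 6 h of calcium return. Os12g0493900, an armadillo-like helical protein (chromosome 12, 18774224 to 18774283), was at least 635-fold higher after resupply (adjusted p = 5.93e-08). The chaperone genes Os06g0474800 and Os01g0606900, of the DnaJ class that assists heat shock protein 70, were 247-fold and 144-fold higher (log2 7.95 ± 0.67 and 7.17 ± 0.75, adjusted p = 1.39e-06 and 1.18e-05). Os01g0971800, similar to two-component response regulator ARR11, was 117-fold higher (log2 6.87 ± 0.59, adjusted p = 1.83e-06), and Os01g0871800 (TGF-beta receptor family) rose by log2 6.61 ± 0.33 (deficient above background on 2 of 3 arrays). The neighbouring early light-inducible genes Os07g0178700 and Os07g0178800 (chromosome 7, 4176461 to 4176520 and 4178899 to 4178958) fell 29.0-fold and 17.8-fold (log2 -4.86 ± 0.31 and -4.15 ± 0.40, adjusted p = 9.70e-08 and 4.94e-06). Os08g0157600 (homeodomain-like) fell 22.1-fold (log2 -4.47 ± 0.15, adjusted p = 1.13e-09) and Os01g0700100 (MtN3 membrane protein) fell 21.4-fold (log2 -4.42 ± 0.16, adjusted p = 1.33e-09).

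Calcium genes were among those that moved within 6 h at day 5, when 4884 of all 32039 genes were called higher and 2560 lower. The plasma membrane calcium pump Os03g0616400 (chromosome 3, 24158204 to 24158263) was 4.90-fold higher (log2 2.29 ± 0.14, adjusted p = 5.30e-08), and the exchanger Os11g0660000 was 3.97-fold lower (log2 -1.99 ± 0.19, adjusted p = 5.27e-06). Of 23 pumps and exchangers 4 were higher and 2 lower (4 and 2 adjusted over the list alone). Annexin Os03g0284900 was 4.21-fold higher (log2 2.07 ± 0.12, adjusted p = 3.29e-08), and calcium-dependent protein kinase Os03g0688300 was 3.18-fold lower (log2 -1.67 ± 0.14, adjusted p = 1.04e-06). Of 18 CBL sensors and CIPK kinases 1 was higher and 5 lower (1 and 7 adjusted over the list alone), with a median of -0.25 (adjusted p = 0.0229, and adjusted p = 0.417 with an estimated correlation). Members were Os01g0292200 (CIPK 1) at -1.14 ± 0.23 and Os05g0534400 (CBL 4) at -0.80 ± 0.18. Of 34 potassium and sodium transport genes 3 were higher and 7 lower (3 and 7 adjusted over the list alone), with a median of -0.15 (adjusted p = 0.0306, and adjusted p = 0.643 with an estimated correlation), and HKT1-like Os06g0701700 changed by -2.46 ± 0.39. Both shifts ended without replicate 1 of the resupplied group (adjusted p of 0.0526 and 0.0924) and under quantile normalization (0.131 and 0.110), and median scaling ended the first (0.0541). The aquaporin Os09g0541000 was 21.1-fold higher (log2 4.40 ± 0.60, adjusted p = 0.000125), and Os09g0287000 (ethylene-responsive factor 5-like) was 4.59-fold higher (log2 2.20 ± 0.19, adjusted p = 2.18e-06).

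Core histones, expansins and lignin enzymes shifted downward at day 5. Of 37 core histones 1 was higher and 15 lower (1 and 18 adjusted over the list alone), with a median of -0.40 (adjusted p = 2.26e-07, and adjusted p = 0.643 with an estimated correlation). Of 51 expansins and xyloglucan endotransglucosylases 0 were higher and 8 lower (0 and 7 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.00147, and adjusted p = 0.734 with an estimated correlation), and expansin-B7-like Os03g0102700 changed by -2.31 ± 0.32. Of 59 lignin and phenylpropanoid enzymes 3 were higher and 19 lower (5 and 19 adjusted over the list alone), with a median of -0.07 (adjusted p = 0.00338, and adjusted p = 0.643 with an estimated correlation). Laccase Os03g0273200 changed by -2.30 ± 0.34 and 4-coumarate-CoA ligase Os02g0697400 by -2.11 ± 0.30. Photosystem genes had 6 higher and 13 lower of 63 (6 and 13 adjusted over the list alone), with a median of -0.18 and adjusted p = 0.000637 (adjusted p = 0.734 with an estimated correlation), and quantile normalization ended this shift (0.242). Of 146 cytosolic ribosomal proteins 21 were higher and 1 lower (19 and 1 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.00140, and adjusted p = 0.926 with an estimated correlation) that median scaling turned to -0.12 (adjusted p = 0.892). With slide as a block the mean shifts were -0.06 (CBL and CIPK), -0.08 (potassium and sodium), -0.34 (histones), -0.06 (expansins), -0.07 (lignin), -0.05 (photosystem) and 0.29 (ribosomal), with adjusted p of 0.0349, 0.0351, 3.87e-07, 0.0300, 0.00129, 0.000527 and 0.00726. Since the values given first are medians and those with the block means, their sizes cannot be compared. The 25 other tested lists had adjusted p of at least 0.0648 without the block.

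At day 5, 10918 probes were called on resupply, 6749 higher and 4169 lower, and 4831 of them changed at least 2-fold. The surplus of higher probes depended on scaling: quantile normalization gave 4402 higher and 6963 lower, median scaling 3188 and 6144, and the median over all tested probes moved from 0.12 to -0.16 and -0.25. Without resupplied day 5 replicate 1 the split was 5237 and 4329, and it was 5116 and 5791 with quantile normalization besides or 4599 and 4830 with median scaling besides. Blocking on slide gave 9724 (6422 higher, 3302 lower), from resupplied replicates 1 and 2 against the 3 deficient arrays. With it 66 of 75 named genes kept the call, all those given here among them. The count was 7151 without deficient day 5 replicate 3 and 17898 without resupplied day 5 replicate 2.

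The same comparison at day 14 asked whether 6 h of resupply acted on seedlings kept deficient for 14 days. Os01g0871800 (TGF-beta receptor family) was 44.2-fold higher after resupply (log2 5.47 ± 0.33, adjusted p = 1.68e-07), and Os03g0760000 (cytochrome P450) was at least 10.3-fold higher (adjusted p = 6.51e-08). Os12g0493900, the armadillo-like protein, and Os07g0628900 (similar to KI domain interacting kinase 1) rose by log2 8.32 ± 0.62 and 7.32 ± 0.63, with the deficient group above background on 2 of 3 arrays (adjusted p = 9.43e-07 and 3.92e-06). Os01g0307500, a cation transporter family protein (chromosome 1, 11506962 to 11507021), was at least 16.6-fold lower (adjusted p = 6.51e-08). The early light-inducible genes Os07g0178700 and Os07g0178800 fell 29.1-fold and 15.9-fold (log2 -4.86 ± 0.31 and -3.99 ± 0.40, adjusted p = 2.66e-07 and 1.23e-05). The pump Os03g0616400 was 3.11-fold higher (log2 1.64 ± 0.14, adjusted p = 2.97e-06), and calcium-dependent protein kinase Os03g0688300 was 2.04-fold lower (log2 -1.03 ± 0.14, adjusted p = 0.000154). Os09g0287000 (ethylene-responsive factor 5-like) was 7.51-fold higher (log2 2.91 ± 0.19, adjusted p = 3.44e-07). The aquaporin Os09g0541000 was 8.53-fold higher (log2 3.09 ± 0.60, adjusted p = 0.00318), a call that ended with slide as a block.

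On resupply at day 14, 2171 of all 32039 genes were called higher and 1744 lower. Of 12 iron uptake and nicotianamine genes 0 were higher and 4 lower (0 and 7 adjusted over the list alone), with a mean of -1.38 (adjusted p = 0.00147, and adjusted p = 0.417 with an estimated correlation). Ferric reductase-like Os04g0444800 was 3.85-fold lower (log2 -1.94 ± 0.20, adjusted p = 1.58e-05), and nicotianamine synthase 2, Os03g0307200, was 13.0-fold lower (log2 -3.70 ± 0.96, adjusted p = 0.0209), a call that the slide block and some single arrays ended. Of 130 heat shock proteins and factors 7 were higher and 24 lower (8 and 27 adjusted over the list alone), with a median of -0.16 (adjusted p = 0.00291, and adjusted p = 0.417 with an estimated correlation). A heat shock protein gene, Os05g0519700 (chromosome 5, 25900747 to 25900806), was 4.11-fold lower (log2 -2.04 ± 0.30, adjusted p = 0.000438), while DnaJ gene Os06g0474800 was 28.4-fold higher (log2 4.83 ± 0.67, adjusted p = 0.000222) and heat shock transcription factor 29-like Os01g0733200 was 12.5-fold higher (log2 3.65 ± 0.21, adjusted p = 1.14e-07). Cytosolic ribosomal proteins had 0 of 146 called by limma (9 higher and 2 lower at an unadjusted p below 0.05), a median of 0.12 and adjusted p = 0.0146 (adjusted p = 0.954 with an estimated correlation). That shift ended under quantile normalization (adjusted p = 0.275), median scaling (0.0792) and normexp (0.0947), and its mean was -0.06 with slide as a block (adjusted p = 0.279). The block left the iron list at a mean of -1.22 (adjusted p = 0.00726) and the heat shock list at -0.24 (0.00129). For the ribosomal and heat shock lists the values with the block are means and those given first are medians. The 29 other tested lists had adjusted p of at least 0.0648 without the block.

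At day 14, 5751 probes were called on resupply, 3065 higher and 2686 lower, and 2317 of them changed at least 2-fold. Blocking on slide gave 3029 (1763 higher, 1266 lower), from 3 resupplied arrays against the single deficient array on their slide, and 38 of 59 named genes kept the call. Median scaling gave 1829 higher and 975 lower (65.2% higher against 53.3%).

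**Figure D4:**
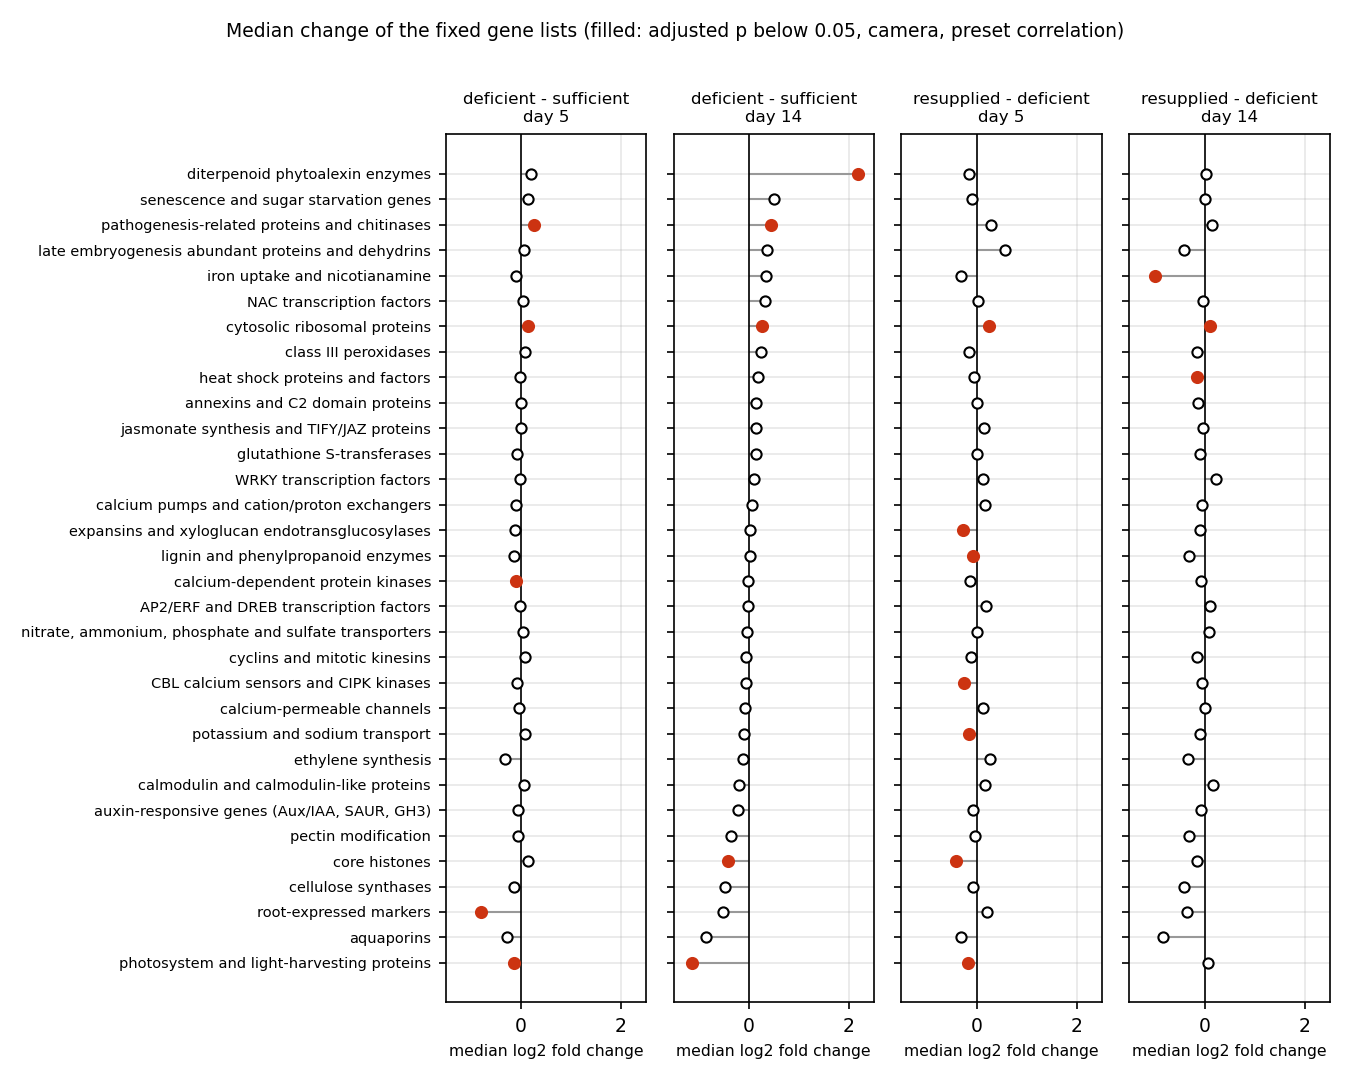
Median log2 fold change of 32 gene lists in the first 4 comparisons; filled points have a camera adjusted p below 0.05 with the preset correlation. The photosystem list lies at -1.14 and the diterpenoid list at 2.17 in deficient against sufficient seedlings at day 14.

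Resupplied seedlings were also set against sufficient ones, to ask how far they stood from seedlings that never lacked calcium. At day 14 no slide held both groups, so without a block treatment and slide cannot be told apart. Their slides were linked only by the deficient day 14 arrays, with 1 of these on slide 3. Results with the block at day 14 therefore lean on that array. At day 5 the armadillo-like Os12g0493900 and the DnaJ gene Os06g0474800 were at least 539-fold and 372-fold higher, and Os07g0178700 (early light-inducible) and Os01g0700100 (MtN3) fell 47.9-fold and 31.3-fold (log2 -5.58 ± 0.31 and -4.97 ± 0.16). At day 14 Os12g0493900 and Os07g0501100 (chalcone synthase 2-like) were at least 331-fold and 93.0-fold higher, Os05g0469600 (pyruvate decarboxylase) was 347-fold higher (log2 8.44 ± 0.66), and Os08g0139700 (terpene synthase 6-like) was at least 188-fold lower. At day 5, 18023 probes were called (11080 higher, 6943 lower; 17381 with slide as a block, 11328 and 6053). Quantile normalization and median scaling turned the surplus (7252 and 10279, 5069 and 10264), and the median over all probes moved from 0.19 to -0.14 and -0.23. Without resupplied day 5 replicate 1, 16828 were called (9381 and 7447), with splits of 8660 and 9242 under quantile normalization and 7510 and 8797 under median scaling. At day 14, 22119 were called (11260 higher, 10859 lower), and 8782 with slide as a block (4048 and 4734), of which 8497 had the same direction as before. All 12 named genes kept the call with the block.

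In these comparisons 74 of 146 ribosomal proteins were higher at day 5 and 1 lower (82 and 1 adjusted over the list alone; mean 0.41, adjusted p = 2.55e-06), a mean that was -0.00 under median scaling. Lists with lower members were the expansins (3 higher, 19 lower of 51), lignin enzymes (10 and 24 of 59), photosystem genes (6 and 26 of 63), core histones (1 and 12 of 37), calcium-dependent protein kinases (3 and 11 of 28) and CBL and CIPK genes (2 and 8 of 18), with adjusted p of 4.48e-05, 0.00169, 4.26e-05, 0.000347, 0.00685 and 0.0168. Adjusted over the list alone, lignin enzymes had 11 and 24, photosystem genes 7 and 27 and calcium-dependent protein kinases 3 and 12, and the other 3 kept their counts. Quantile normalization ended the last 4 of these (0.107, 0.129, 0.306 and 0.0691). Auxin-responsive genes (9 higher, 15 lower of 53; 9 and 17 adjusted over the list alone) and heat shock genes (23 and 33 of 130; 25 and 35) were shifted downward by the test (adjusted p of 0.0180 and 0.0319). Their means were -0.00 and 0.09, and both shifts ended without resupplied day 5 replicate 1 (0.0920 and 0.105). At day 14 photosystem genes had 8 higher and 42 lower (median -1.04, adjusted p = 7.57e-09), ribosomal proteins 75 and 3 (0.40, 3.24e-07), histones 2 and 19 (-0.53, 0.00290), chitinases and related proteins 39 and 11 (0.77, 0.00162), diterpenoid enzymes 9 and 1 (2.24, 0.00414) and aquaporins 0 and 5 (-1.28, 0.0134). Adjusted over the list alone, ribosomal proteins had 79 and 3 and the chitinase list 41 and 12, and the other 4 kept their counts. The estimated correlation gave these 15 shifts adjusted p of 0.597 to 0.740. With slide as a block the 9 shifts at day 5 kept adjusted p of 3.83e-05 to 0.0250. Of those at day 14, the ribosomal list lost its shift (0.315) and the other 5 kept adjusted p of 8.12e-11 to 0.0215.

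Comparisons of days asked whether the deficiency effect and the resupply effect differed between day 14 and day 5. For deficiency 5067 probes differed, 1947 higher and 3120 lower, and 3582 with slide as a block (1246 and 2336), of which 3366 were the same probes in the same direction. Without resupplied day 5 replicate 1 and with median scaling the split was 3461 and 3272. The count was 3179 without sufficient day 5 replicate 2 and 3152 without deficient day 5 replicate 3. For resupply 1012 probes differed, 489 higher and 523 lower, and 333 with the block (134 and 199). Median scaling gave 533 higher and 173 lower for resupply, quantile normalization 656 and 348 and normexp 560 and 355, and the median over all probes moved from -0.16 to 0.26 under median scaling and 0.12 under quantile normalization. Without resupplied day 5 replicate 1 median scaling gave 957 and 425, and quantile normalization 1093 and 610. The count for resupply was 561, 507 and 254 without deficient day 5 replicate 1, 2 and 3, 566 and 504 without deficient day 14 replicate 1 and 2, 417 and 482 without resupplied day 14 replicate 1 and 3, and 7192 without resupplied day 5 replicate 2.

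Sufficient seedlings at day 14 were compared with those at day 5 as the background of age, although these groups also lay on different slides. Os12g0555100, similar to probenazole-inducible protein PBZ1, a defence protein (chromosome 12, 22734801 to 22734860), was at least 106-fold lower at day 14 (adjusted p = 2.47e-05), and Os03g0197200, similar to a sorbitol transporter, was at least 4.74-fold higher (adjusted p = 0.00149). Of 28 calcium-dependent protein kinases 0 were higher and 8 lower (0 and 11 adjusted over the list alone; adjusted p = 0.000142), of 37 core histones 1 and 12 (1 and 21; 3.81e-07) and of 30 cyclins and mitotic kinesins 0 and 9 (0 and 11; 0.00335), and the estimated correlation gave adjusted p of 0.597, 0.637 and 0.637. These 3 kept their shifts with slide as a block (3.83e-05, 1.80e-06 and 0.0126). Iron uptake (3 higher, 0 lower; mean 1.22), late embryogenesis (1 and 1; 1.28), photosystem (3 and 2; 0.21) and expansin lists (1 and 9; -0.37) had adjusted p of 0.0229, 0.00503, 0.0183 and 0.0183 (0.618, 0.637, 0.654 and 0.653 with an estimated correlation). Adjusted over the list alone they had 4 and 1, 10 and 1, 3 and 2, and 2 and 11. All 4 lost the shift with the block (0.177, 0.148, 0.412 and 0.974), where the expansin mean was 0.36. In total 5656 probes were called (2986 higher, 2670 lower), and 80 with the block. No slide held both groups, and slides 1 and 2 were linked only by the resupplied day 5 arrays, the unusual replicate 1 among them. Calls and shifts kept or lost with the block therefore say little about this comparison. Without the block, age and slide cannot be told apart, so the counts, folds and list shifts may reflect either. Median scaling gave 1034 higher and 1581 lower (39.5% higher against 52.8%), and 3732 and 5309 without resupplied day 5 replicate 1. The count was 2514, 3158 and 3088 without sufficient day 5 replicate 1, 2 and 3, 2988, 3303 and 3378 without sufficient day 14 replicate 1, 2 and 3, and 9099 without resupplied day 5 replicate 1. Of 6 named genes, Os12g0555100 alone kept the call with the block.

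The lists of called genes were compared over 32039 genes, one probe each. Deficiency at day 5 and day 14 shared 226 higher and 278 lower genes, where independent lists would share 61.6 and 67.3, and 14 and 11 genes were called in opposite directions. Across genes the log2 fold changes correlated at r = 0.454 (simulated -0.00). Resupply at day 5 and day 14 shared 1470 higher and 886 lower genes (331 and 139 for independent lists), with 24 and 30 in opposite directions and r = 0.402 (0.496 without resupplied day 5 replicate 1). Deficiency and resupply of the same day share the deficient arrays, which gave r = -0.502 and -0.497 in 20 simulations without any effect. The measured r were 0.09 at day 5 and -0.01 at day 14, and the covariance exceeded the simulated one by 0.134 and 0.0881. The simulation gave all arrays the same pooled spread, which resupplied day 5 replicate 1 widened. If the deficient arrays varied less, the simulated r and covariance are too negative and this excess is too large. At day 14, 559 genes were higher in both and 705 lower in both (390 and 293 for independent lists), while 256 and 441 moved in opposite directions (313 and 364).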

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

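The results in this part were set apart because an effect differed between day 14 and day 5 in a direct test of the difference, in which a positive log2 value means a higher effect at day 14. The tests of slides and of tissue share were chosen only after the result was seen, whereas the splits of the arrays were planned.

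The effect of deficiency differed between days for 5067 probes. Its largest named differences were log2 7.90 ± 1.19 SE for Os01g0342900 (similar to an AMP-binding protein), 7.55 ± 1.54 for Os08g0473900 (alpha amylase isozyme 3D-like) and 7.07 ± 1.17 for Os03g0269300 (protein kinase-like), with adjusted p of 0.00135, 0.00706 and 0.00219. In the other direction they were -10.13 ± 2.79 for Os12g0247700 (similar to jasmonate-induced protein), -8.76 ± 1.21 for Os02g0240300 (class III peroxidase) and -7.62 ± 1.40 for Os02g0308400 (FAS1 domain), with adjusted p of 0.0328, 0.000902 and 0.00398. Os01g0342900 was well above background on 0 of 3 arrays in sufficient and deficient seedlings at day 5 and in sufficient seedlings at day 14. For Os03g0269300 these were 1, 1 and 0 of 3 arrays. In deficient seedlings at day 14 Os02g0240300 was well above background on 2 of 3 arrays and Os02g0308400 on 1. The sizes for these genes are therefore uncertain. Os12g0247700 lost the call with slide as a block, under quantile normalization and when single arrays were left out.

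By list, photosystem genes had the smallest adjusted p for the difference in deficiency effect, with 0 higher and 35 lower of 63 (3 and 43 adjusted over the list alone) and a mean of -0.89 (adjusted p = 2.74e-16, and 0.597 with an estimated correlation). Diterpenoid enzymes had 4 higher and 0 lower of 12 (8 and 0 adjusted over the list alone), with a mean of 1.70 (4.49e-05 and 0.625). Core histones had 0 and 7 of 37 (0 and 11), with a mean of -0.58 (2.21e-05 and 0.637), and heat shock genes 12 and 7 of 130 (25 and 12), with a mean of 0.28 (0.0198 and 0.618). Ribosomal proteins had 0 and 0 of 146 called by limma (2 and 1 at an unadjusted p below 0.05), with a mean of 0.12 (0.0168 and 0.835) that ended with slide as a block (0.04, adjusted p = 0.458) and under quantile normalization (0.112). The block left the other 4 means at -0.89, 1.79, -0.60 and 0.27, with adjusted p of 1.95e-16, 6.02e-05, 4.12e-06 and 0.0424.

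The effect of resupply differed between days for 1012 probes. The named genes were Os02g0251800 (VQ domain) at 2.87 ± 0.62, Os07g0611500 (C1-like domain) at 2.74 ± 0.31, Os04g0419900 (receptor-like kinase) at 2.72 ± 0.55, Os02g0179500 (Hly-III related) at -5.15, Os05g0470800 (surface antigen D15 family) at -4.72 and Os01g0307500 (cation transporter) at -4.47. For the last 3 genes resupplied seedlings at day 14 were well above background on 0 of 3 arrays, so only the direction of these differences is read and their sizes are uncertain. Deficient seedlings at day 5 were so on 0 of 3 arrays for Os02g0179500 and Os05g0470800, and at day 14 on 1 of 3 for Os05g0470800. For Os05g0470800 all 3 resupplied arrays at day 5 were above it, the unusual replicate 1 among them. The adjusted p of the named genes, in the order given, were 0.0334, 0.00121, 0.0257, 0.0240, 0.0241 and 0.000872. With slide as a block Os07g0611500 and Os01g0307500 kept the call and the other 4 lost it, as they did when some single arrays were left out, and quantile normalization ended those of Os02g0179500, Os05g0470800 and Os01g0307500. List means were 0.088 for photosystem genes, 0.19 for core histones, 0.19 for expansins, -0.090 for lignin enzymes, -0.085 for nitrate, ammonium, phosphate and sulfate transporters and 0.031 for class III peroxidases. Over all 32039 genes 317 were called higher and 360 lower. Called members were, in the order of the lists, 1 higher and 0 lower of 63, 2 and 0 of 37, 3 and 0 of 51, 3 and 1 of 59, 2 and 2 of 42, and 5 and 1 of 110. Adjusted over the list alone these were 1 and 0, 5 and 0, 3 and 0, 6 and 1, 4 and 3, and 11 and 3. Camera compares a list with other genes, and the median over all tested probes was -0.156 (-0.052 without resupplied day 5 replicate 1). An upward call can therefore mean only that a list lay less far down than other genes. The fry test, which does not compare with other genes, called 1 of 32 lists. Camera pointed upward for all 6, against the sign of the mean for lignin enzymes and ion transporters and of the median for peroxidases (-0.045). Its adjusted p were 4.39e-05, 9.14e-05, 0.00231, 0.0114, 0.0289 and 0.0456 (0.637 with an estimated correlation). With the block the last 4 ended (0.741, 0.0884, 0.126 and 0.574), and the expansin and peroxidase means were -0.22 and -0.22. Quantile normalization ended all but the expansin shift (0.319, 0.114, 0.305, 0.279 and 0.230).

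More probes responded to deficiency at day 14 than at day 5. Against slides hybridised apart as the whole cause, 66.4% of the calls of the difference, 3366 of 5067, were kept with slide as a block. A smaller share of green tissue would raise root transcripts; of 7 root-expressed markers 1, a DNA repair helicase, was called higher in deficient seedlings at day 14 and 3 were lower, with a median of -0.51, so members went both ways and this explanation cannot be told apart from regulation. Of 100 splits of the arrays, 3 gave as many probes, the real one included, a share under 0.05, and the highest other gave 10602. Such splits also mix the main effects of deficiency and day, so they are no test of chance for this difference, and chance is not excluded. The longer time without calcium and the age of the seedlings may both contribute, and the design does not separate these.

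For the difference in resupply effect, 5 of 100 splits gave as many as 1012 probes, the real one included, and chance cannot be excluded. The highest other split gave 20200, which points to a structure of the arrays. Such splits also mix the main effects of resupply and day, so they are no test of chance for this difference, and what made that count was not tested.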

How the results depend on the processing

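The alternatives that single out resupplied day 5 replicate 1, and the slide block for the gene lists, were chosen only after the data were seen. Normexp correction, quantile normalization, the value table of the authors, the filter on all 18 arrays, removal of outlier spots and the trended, robust prior each kept the 9 counts of called probes within 1.5 times. Where a count moved further, the cause was not tested unless a reason is given.

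Median scaling lowered the count to 555 for deficient against sufficient at day 5, 11456 at day 14, 2804 for resupplied against deficient at day 14, 2204 for the difference in deficiency effect and 2615 for day 14 against day 5 in sufficient seedlings. Without a filter, which adds tests of dim probes, the count was 626 for deficient against sufficient at day 5 and 535 for the difference in resupply effect.

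A slide block gave 3029 for resupplied against deficient at day 14, where 3 arrays and 1 shared a slide, 8782 for resupplied against sufficient at day 14, 333 for the difference in resupply effect and 80 for day 14 against day 5. Under it the mean of the cytosolic ribosomal proteins on resupply at day 14 was -0.063, against 0.10.

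Array weights, which ran from 0.105 for resupplied day 5 replicate 1 to 8.46 for resupplied day 14 replicate 1, raised the count to 5984 for deficient against sufficient at day 5, 11767 for resupplied against deficient at day 14, 9754 for the difference in deficiency effect, 5055 for that in resupply effect and 12179 for day 14 against day 5. Leaving out resupplied day 5 replicate 1 gave 1951 for deficient against sufficient at day 5 and 9099 for day 14 against day 5. With quantile normalization besides, these were 2106 and 8790, and 1703 for the difference in resupply effect. With median scaling besides, they were 2066 and 9041.

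Fitting only the arrays of the groups compared gave 1960 for deficient against sufficient at day 5, 4311 for resupplied against deficient at day 5, 11579 for resupplied against sufficient at day 5, 178 for the difference in resupply effect and 8872 for day 14 against day 5.

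A minimum change of 2-fold, which can only lower a count, gave 594 and 7579 for deficient against sufficient at day 5 and day 14, 4831 and 2317 for resupplied against deficient, 8857 and 11244 for resupplied against sufficient, and 2148 for day 14 against day 5. An adjusted p below 0.01 gave 154 and 11391 for deficient against sufficient, 5685 and 3082 for resupplied against deficient, 11270 for resupplied against sufficient at day 5, 1933 and 128 for the differences in deficiency and resupply effect, and 1501 for day 14 against day 5.

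Leaving out single arrays gave 176 (sufficient day 5 replicate 1) to 1951 (resupplied day 5 replicate 1) for deficient against sufficient at day 5 and 13590 to 20127 at day 14. For resupplied against deficient it gave 7151 (deficient day 5 replicate 3) to 17898 (resupplied day 5 replicate 2) at day 5 and 4208 to 7420 at day 14. Resupplied against sufficient ranged from 13462 to 23420 at day 5 and 19024 to 25277 at day 14. The difference in deficiency effect ranged from 3152 (deficient day 5 replicate 3) to 6673, that in resupply effect from 254 (deficient day 5 replicate 3) to 7192 (resupplied day 5 replicate 2), and day 14 against day 5 from 2514 (sufficient day 5 replicate 1) to 9099 (resupplied day 5 replicate 1).

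Of 20 gene list shifts in the first 4 comparisons, 0 were kept by camera with an estimated correlation, 10 by fry, 14 under quantile normalization, 17 with median scaling, 18 without resupplied day 5 replicate 1, 19 with normexp or a slide block and 20 with the mean of the probes of each gene. Other lists called besides these numbered 13 by fry, 3 under quantile normalization, 3 with median scaling, 1 with normexp, 4 with a slide block and 6 with the mean of the probes.

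Of 286 calls of named genes, 263 were kept with normexp, 251 with quantile normalization, 245 with median scaling, 266 without a filter, 237 with a slide block, 280 without resupplied day 5 replicate 1, and 250 to 280 with single arrays left out. The filter on all 18 arrays kept 187, since it removes genes near background in any group. Os11g0136600 (calcium-dependent protein kinase) turned on resupply at day 5, from 1.26 to -0.30, under quantile normalization.

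Replicate numbers did not pair the arrays, as the correlations of their deviations were -0.12 to 0.12. A replicate block kept 278 named calls.

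Signal over background limits the folds of genes that lie near background in a group. At 3 arrays per group, simulated 2-fold changes were recovered in 25.4% of cases for the difference in deficiency effect and 11.9% for that in resupply effect. The simulation changed far fewer probes than were called, with noise alike on all arrays, so these rates do not measure how many real differences were found.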

Other observations

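All tests of the genes that moved the same way at both days, and those of an additive background and of resupply on the unusual array, were chosen only after the result was seen; the first test of genomic DNA and the splits of arrays were planned.

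Resupplied day 5 replicate 1 read dim probes brighter than the other arrays, with a lower-quartile signal of 231 against 11.8 to 31.6 and an array weight of 0.105. An even additive background does not account for it, since negative controls rose by 17.8 and the lower quartile by 215, a ratio of 0.0830. Genomic DNA would raise contiguous probes more than intron-spanning ones, but among probes well above background on this array alone the difference in excess was log2 -0.42 ± 0.15 (4.01 against 4.44), opposite to that need, and it was -0.55 ± 0.16 over all probes dim on the other 17 arrays, a test added later that does not select on this array. The outcome stated beforehand for no such DNA, a difference under 0.1, was not met either, and the reading of a negative value as evidence against it was set after the value was seen. Resupply itself is an unlikely source, since replicates 2 and 3 of the group reached 75.7% and 83.2% of spots well above background against 98.9%, and the bound for this test was also set after the values were seen.

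Genes that changed the same way 6 h after resupply at both days numbered 2356 without a block (470 for independent lists). With slide as a block there were 1386 (235 for independent lists, 44 in opposite directions), and 1284 were in both counts, which argues against slides hybridised apart as the whole source, although at day 14 the block left 1 deficient array, assumed to vary like the others. At day 5 the block left resupplied replicates 1 and 2, so its fold changes lean partly on the unusual replicate 1. A return to the sufficient level is unlikely to describe most of the genes that moved the same way, since 10.4% at day 14 and 4.46% at day 5 lay closer to the sufficient group after resupply. Of 4 measured clock genes 0 were called by limma in the same direction at both days (0 also at an unadjusted p below 0.05). EARLY FLOWERING 4-like Os11g0621500 was called on resupply at day 14, and no single array left out ended that call. The labels do not state the hour of harvest, and resupplied seedlings may have been collected 6 h later, so time of day cannot be told apart from calcium return.

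For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. Every other split mixes both groups, so a real difference between them widens the spread and holds the count down. The low counts of other splits are therefore no evidence against chance. Real and highest other counts of called probes were 1153 and 1 for deficient against sufficient at day 5, 17273 and 0 at day 14, 10918 and 1 for resupplied against deficient at day 5 and 5751 and 2 at day 14. They were 18023 and 1 for resupplied against sufficient at day 5, 22119 and 0 at day 14, and 5656 and 0 for day 14 against day 5 in sufficient seedlings.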
